A study of Mus musculus with 29 samples.

How the data were processed

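Chromatin immunoprecipitation sequencing (ChIP-seq) of mouse C57BL/6 cells was analysed in 22 libraries. Of these, 14 measured acetylation of histone H3 at lysine 27 (H3K27ac) in 7 groups of 2 libraries, and 8 measured binding of the transcription factors IRF8 and CEBPA, with 2 libraries per factor and cell type. The labels speak of biological duplicates and do not say whether the 2 libraries of a group came from different animals, so the p-values between groups can rest on technical spread only. The 7 input DNA samples were not analysed here as libraries of their own.

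Per the labels, the authors aligned the reads to mm10 (GRCm38) with Bowtie 1.1.2 and called regions with HOMER 4.9 in each library on its own. H3K27ac regions were called in the histone style against input DNA, with a peak size of 500 bases and at least 4-fold enrichment over input. IRF8 peaks were called in the factor style without input, and CEBPA peaks in the factor style with input. The second CEBPA library of each cell type was called against the input of the first. In the deposited lists, the columns of start and end hold genome positions, a unit of the kind other, in bases. The deposited score column holds the same value for each region, so no region had a strength beyond its width. Total tags and the percentage of tags in called regions were read from the comment lines of the deposited lists. Depth per group stands at the start of the report; 95% intervals of shares are Wilson intervals and cover counting error only.

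The H3K27ac regions of the 14 libraries were merged into 112928 regions with a median width of 501 bases. A merged region was given to the protein-coding gene with the nearest span within 100000 bases of the region's midpoint. The annotation table at hand held gene spans without strand, so the distance was taken to the span and not to the transcription start that had been planned. It held 21896 protein-coding genes, and 85.3% of the merged regions were assigned, to 17195 genes. The value of a gene was the number of bases covered by a library's called regions at its locus, scaled to the mean total covered length of the libraries and given here as scaled kb. For Irf8 this value took in the +56 kb element. It left out upstream regions nearer to another gene, such as those called near -50 and -40 kb. Genes with covered bases in at least 2 libraries were kept, which left 15121. The log2 of the covered bases plus 1000 was fitted by group with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust set), over all 14 libraries with 7 residual degrees of freedom. There were 8 comparisons of groups, each adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Differences on the log2 scale are given with limma's standard error, and levels as mean ± SD of 2 libraries. A group whose libraries were both listed at 0 is given as such, without a fold.

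The following choices were fixed before the data were examined: the comparisons, the tests, 15 gene lists of 12 to 26 genes and the rule for named genes. The lists were HSC and multipotent progenitor, lymphoid priming, cDC1, pan-DC, plasmacytoid DC, monocyte and macrophage, neutrophil and granule, B cell, T and NK cell, erythroid and megakaryocyte, mast cell and basophil, interferon response, MHC class I presentation, lineage transcription factor, and housekeeping genes. Each list was tested in each comparison by limma's camera with a preset inter-gene correlation of 0.01 and again with an estimated correlation (120 tests each), and by Fisher's exact test of its calls (240 tests), with adjustment within each family. Some genes stand in more than 1 list, such as Irf8 and Flt3.

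Irf8 was always named, also where it had no call. There it counts among the named genes of a comparison, though it had no call to lose. In each comparison the 10 highest and the 10 lowest genes by log2 difference could be named among those with an adjusted p under 0.05 whose 2 groups did not overlap. List members past the threshold could be named as examples of their list; had fewer than 5 genes passed in a direction, the 5 with the smallest p would have been named as not passing. For transcription factor peaks, the 10 genes with the most reproducible peaks of a set could be named, together with list members. For LMPP regions, the 5 widest lost and the 5 widest gained of each comparison could be named.

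Similarity of libraries was the Jaccard index of covered bases, tested by exact permutation over all pairings of the 14 libraries. Windows of 4 kb were laid at Irf8 on its start coordinate and at -50, +32, +41 and +56 kb from it. LMPP regions were counted as lost or gained when called in both libraries of a group and in neither of the other; 2 against 2 libraries give no two-sided permutation p below 0.333, so none is given. Reproducible peaks of a factor were merged peaks with a call in both libraries, overlapping by at least 1 base. Overlaps were set against 1000 random placements, each peak being moved to the same offset from a randomly drawn protein-coding gene, so that 0.001 is the smallest p they can give. Shares of peaks or regions were compared by Fisher's exact test, two-sided, with peaks and regions as units that are not replicates. Genes with a peak were compared with list membership over 21896 genes (60 tests). A planned search for sequence motifs was not run, since it needs a genome sequence.

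Alternatives fixed with the plan were another pseudocount (200 bases), no filter, quantile normalization, no scaling, an equal number of regions per library (the 16469 widest), assignment within 20000 bases, a replicate block, a fit of the 4 libraries compared, each library left out in turn, other overlap rules and stricter peak lists. Stricter peak lists took the first part of each list in deposited order, since no score ranks the peaks, and that order is not known to rank them either. Added after the data were seen were regions called in both replicates of a group, the equal number in deposited order, tags in called regions as a covariate, the LMPP groups of low enrichment left out, WT LSK in place of WT LMPP, genes on X and Y left out, and stratification by width. Where leaving out a library left 1 in its group, that library was assumed to vary like the other groups.

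The limma fit was tested on simulated data with known changes and recovered 95 to 96% of changes of 2 on the log2 scale and 45 to 47% of changes of 1, with 5 to 7 false calls among 15121 genes. The changed genes were drawn only from well covered ones, with normal noise of equal spread in all groups. Real values held many zeros, and the replicate Jaccard index ran from 0.256 in IRF8KO LMPP to 0.646 in WT LSK. The rates may thus not hold for the LMPP comparisons. Interval overlaps were checked on 200 simulated sets against a plain count, with 0 mismatches, and no 2 of the 22 lists were identical. Deviations of replicates from their group means correlated between groups at -0.05 to 0.08, so the replicate numbers did not pair libraries across groups. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9 were used.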

Results

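H3K27ac, a mark of active promoters and enhancers, was mapped in mouse blood progenitors and dendritic cells, and binding of IRF8 and CEBPA in mature myeloid cells. The wild-type (WT) H3K27ac groups were LSK cells (lineage-negative, Sca-1 and CD117 positive stem and multipotent progenitors), lymphoid-primed multipotent progenitors (LMPP) and type 1 classical dendritic cells (cDC1). Mice without the enhancer 56 kb downstream of Irf8 (d56kb) gave LMPP, granulocyte-monocyte progenitors (GMP) and monocyte-dendritic cell progenitors (MDP), and IRF8KO mice, which lack the factor, gave LMPP. IRF8, a transcription factor needed for cDC1 and monocyte development, and CEBPA, a transcription factor of the granulocyte and monocyte lineages, were mapped in WT cDC1 and WT monocytes (Mo). Each group had 2 libraries. Progenitors and Mo came from bone marrow and cDC1 from spleen, so that cDC1 and LMPP also differed in organ. WT GMP and WT MDP were not analysed here, which leaves the effect of the deletion untested in those cells.

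The H3K27ac libraries differed in depth and enrichment between groups. Total tags were 7.74 ± 0.785 M in WT LSK, 2.82 ± 1.16 in WT LMPP, 8.15 ± 3.86 in WT cDC1, 3.33 ± 0.488 in d56kb LMPP, 2.82 ± 0.295 in d56kb GMP, 2.59 ± 1.07 in d56kb MDP and 1.36 ± 0.150 in IRF8KO LMPP (SD, n = 2). The share of tags inside called regions was 37.9 ± 5.38% in WT LSK, 19.4 ± 6.16% in WT LMPP, 34.4 ± 25.4% in WT cDC1, 37.4 ± 0.903% in d56kb LMPP, 54.1 ± 1.49% in d56kb GMP, 44.8 ± 3.65% in d56kb MDP and 18.2 ± 0.576% in IRF8KO LMPP. The 2 WT cDC1 libraries held 5.42 and 10.9 M tags, with 52.3 and 16.4% in called regions. Called regions covered 18.0 ± 0.509 Mb in IRF8KO LMPP, 23.6 ± 1.96 Mb in WT LMPP, 36.6 ± 2.17 Mb in d56kb LMPP and 48.3 ± 5.37 Mb in WT LSK. The IRF8 libraries held 13.2 ± 1.30 M tags in cDC1 and 14.7 ± 1.87 M in Mo, and the CEBPA libraries 20.6 ± 18.0 M in cDC1 and 19.8 ± 3.95 M in Mo.

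Libraries of the same cell type and genotype shared more acetylated bases than other pairs. The mean Jaccard index of the 7 same-group pairs was 0.504, against a mean of 0.330 over all 135135 ways to pair the 14 libraries (exact permutation p = 7.40e-06, one-sided). The replicates of WT LSK were the most alike at 0.646, followed by d56kb GMP at 0.604. The LMPP groups were less well separated: WT LMPP replicates shared 0.389 with each other and 0.387 with d56kb LMPP, and IRF8KO LMPP replicates shared 0.256 with each other and 0.291 with WT LMPP. WT LSK and d56kb LMPP shared 0.538, close to the 0.543 between d56kb LMPP replicates. Of the IRF8KO LMPP regions, 45.1% and 44.4% were called in no other library.

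**Figure D1:**
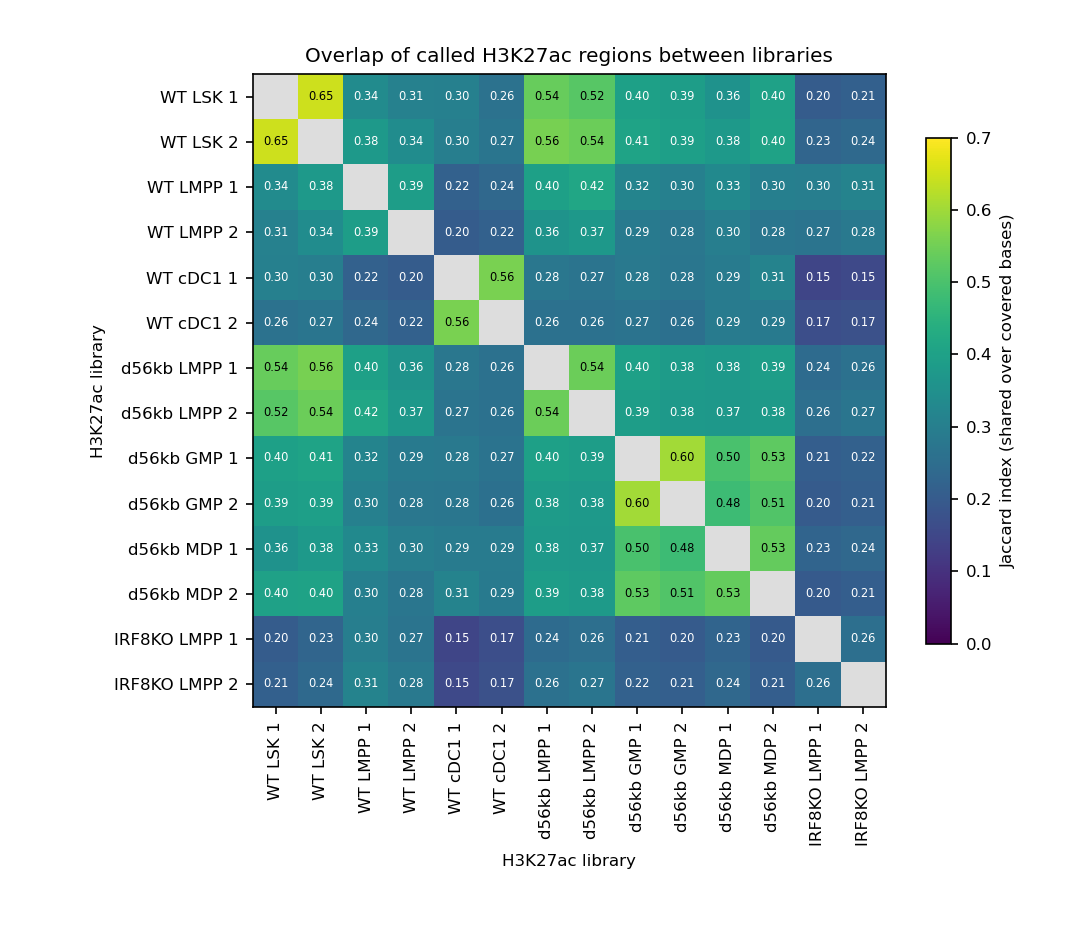
Heatmap of the Jaccard index (shared over covered bases, no unit) between the called H3K27ac regions of each pair of the 14 libraries, with libraries on both axes and the index as colour. Replicates of WT LSK reached 0.646 and those of IRF8KO LMPP 0.256.

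Acetylation at Irf8 itself differed between cell types. The gene lies on chromosome 8 from 120736358 to 120756694. At +56 kb, the element that is deleted in d56kb mice, 6 of 6 WT libraries and 0 of 6 d56kb libraries had a called region, which the deletion itself requires and which checks the labels only. Covered bases in that window were 1206.5 ± 634 in WT LSK, 725.5 ± 118 in WT LMPP and 1633.5 ± 961 in WT cDC1 (SD, n = 2). The element was also without a call in both IRF8KO LMPP libraries, a difference from the 2 WT LMPP libraries that was not tested, in libraries where 34.5% of comparably narrow WT LMPP regions went uncalled. The window at +32 kb was called in cDC1 (3494 ± 716 bases) and d56kb MDP (909 ± 132 bases), and the window at +41 kb in cDC1 (3258 ± 320 bases). At -50 kb the most covered group was d56kb MDP, with 3013.5 ± 9.19 bases against 816.5 ± 62.9 in d56kb GMP. The start of Irf8 was covered by 2625.5 ± 139 bases in cDC1 and 837.5 ± 275 in d56kb MDP, and was without a call in WT LSK, WT LMPP, d56kb GMP and IRF8KO LMPP.

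Peaks called at the locus differed by factor and cell type, in libraries that also differed in enrichment. In both cDC1 libraries IRF8 peaks lay at -27, +27, +32 and +41 kb, and +56 kb held a peak in the second cDC1 library and the first Mo library. CEBPA peaks lay in both Mo libraries at -50, -38.7, -34, +4.7, +41 and +56 kb, and in neither cDC1 library.

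**Figure D2:**
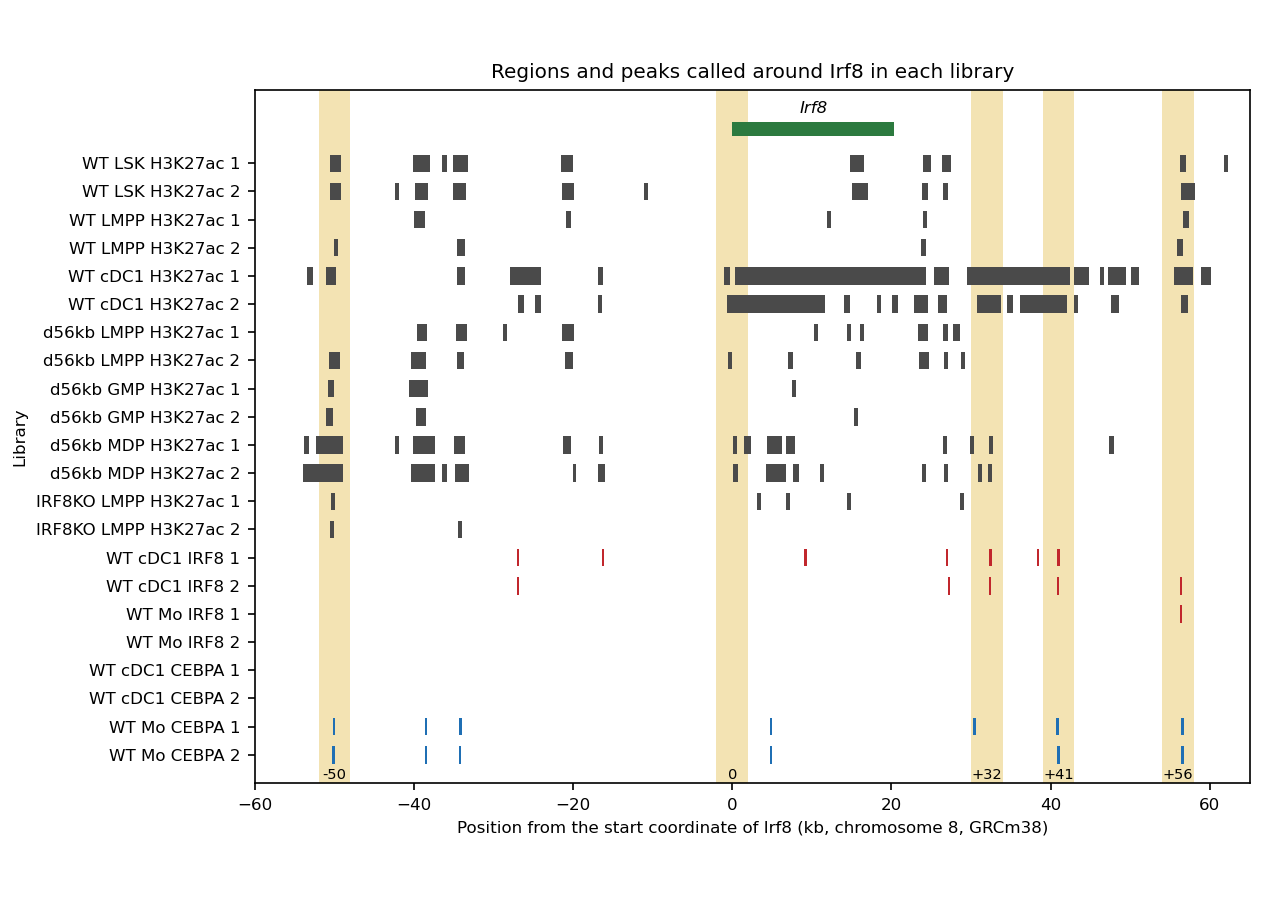
Called regions from 60 kb before to 65 kb after the start of Irf8 on chromosome 8 (x axis, kb), with a line per library: H3K27ac in grey, IRF8 in red, CEBPA in blue, the span of Irf8 in green and the tested windows of 4 kb in yellow. At +56 kb a grey region stands in the 6 WT libraries and in none of the 6 d56kb libraries.

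WT LMPP were compared with WT LSK, whose libraries were deeper and more enriched, so values of 0 in LMPP can be missed calls. Of the lists, only the HSC and multipotent progenitor genes were lower in LMPP by both camera settings. Single genes of other lineages were lower too. Hlf, a transcription factor of haematopoietic stem cells, fell from 15.5 ± 0.55 scaled kb in LSK to 3.82 ± 1.1 in LMPP (SD, n = 2; log2 difference -1.79 ± 0.24, adjusted p = 0.0082). Esam, a surface protein of stem cells, covered 1.93 ± 0.57 kb in LSK and was listed at 0 in both LMPP libraries. Ms4a2, a chain of the IgE receptor of mast cells, covered 2.3 ± 0.14 kb in LSK and Lyz2, the lysozyme gene of myeloid cells, 1.13 ± 0.48 kb, and both were listed at 0 in LMPP. Hbb-bt, an adult beta-globin gene, fell from 3.93 ± 0.53 to 0.394 ± 0.56 kb. Slc26a9, Thbs1 and Arl5c covered 4.32 ± 0.16, 2.78 ± 0.63 and 2.84 ± 0.084 kb in LSK and were listed at 0 in LMPP. Gcnt1, Cask and Ptpn21 fell by 2.39, 2.18 and 2.06 on the log2 scale. In d56kb LMPP, Hlf, Ms4a2, Thbs1 and Slc26a9 were called higher than in WT LMPP (10.3, 2.26, 4.98 and 4.8 kb). Esam, Lyz2 and Hbb-bt were not.

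The genes with the largest gains in LMPP included genes of long span, and no list covered them. Lrp1b, a receptor of the LDL receptor family, rose from 0.166 ± 0.23 to 6.92 ± 3.8 kb (log2 difference 2.69 ± 0.40, adjusted p = 0.0123). Lsamp, a neuronal adhesion protein, rose from 1.16 ± 0.2 to 8.74 ± 1.8 kb, Cdh13, a cadherin, from 0.194 ± 0.27 to 5.71 ± 2.0 kb, and Sgcd, a sarcoglycan of muscle, from 0.194 ± 0.27 to 4.64 ± 0.13 kb. Lingo2 and Csmd1, membrane proteins of neurons, rose by 2.51 ± 0.52 and 2.26 ± 0.37. Cdh4, a cadherin, and the glutamate receptor genes Grm7 and Grik1 covered 3.35 ± 1.4, 3.13 ± 1.1 and 2.75 ± 0.19 kb in LMPP and were listed at 0 in LSK. The median span of genes called higher was 50.4 kb and of genes called lower 34.5 kb, against 25.8 kb for all tested genes. Calls at the minimum width of 501 bases made up 51.0 ± 7.96% in WT LMPP and 22.5 ± 2.54% in WT LSK. These gains can therefore rest on scattered narrow calls over long genes, which was not tested here. Called genes had a larger median span than all tested genes in each comparison and direction except those lower in IRF8KO LMPP. Irf8 covered 3.26 ± 2.0 kb in LMPP and 5.54 ± 1.2 kb in LSK and did not pass (log2 difference -0.69 ± 0.62, adjusted p = 0.58), except without scaling (-1.52).

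Of the lists, the HSC and multipotent progenitor genes were lower in LMPP as a group (camera adjusted p = 0.00114; adjusted p = 0.0412 with an estimated correlation). Of its 22 measured members 2 were called lower, and 5 adjusted over the list alone. Erythroid and megakaryocyte genes (1 of 13 lower, and 1 adjusted over the list alone) had a camera adjusted p of 0.00302, but an adjusted p = 0.0769 with an estimated correlation. Mast cell and basophil genes (1 of 9 lower, 3 adjusted over the list alone) had 0.0221, but an adjusted p = 0.115 with an estimated correlation. The lymphoid priming genes leaned lower (camera adjusted p = 0.0362; adjusted p = 0.472 with an estimated correlation), with 0 of 16 called by limma over all genes; adjusted over the list alone 5 were lower and 1 was higher. The 10 lists without a call, lymphoid priming included, held 165 members, of which 37 had an unadjusted p under 0.05.

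In all, 113 genes were higher and 175 lower in LMPP by limma, and 2878 genes had an unadjusted p under 0.05. Irf8, counted among the named genes below, was not called and had no call to lose. Without scaling the median of all genes moved to -0.49 and the calls to 216 higher and 4527 lower; the count was 1541 with regions of both replicates, 109 with a replicate block, 0 in a fit of the 4 libraries (3204 at an unadjusted p under 0.05) and 0 with tags in called regions as a covariate (466). Leaving out the first or the second WT LSK library left 0 calls (1534 and 1829 at an unadjusted p under 0.05), and without the second WT LMPP library 125 were left. Of the 21 genes named here, 20 lost their call without either WT LSK library, and 7 and 11 without the first and the second WT LMPP library.

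WT cDC1 were compared with WT LMPP to describe the enhancer landscape of the mature cell against a progenitor. All 20 cDC1 genes were higher in cDC1, and 16 of 22 HSC and multipotent progenitor genes were lower and 3 higher. Cadm1, an adhesion molecule of cDC1, rose from 0.361 ± 0.51 to 67.5 ± 5.0 scaled kb (SD, n = 2; log2 difference 5.70 ± 0.31, adjusted p = 5.25e-07). Irf8 rose from 3.26 ± 2.0 to 35.0 ± 3.7 kb (log2 difference 3.16 ± 0.62, adjusted p = 0.00274). Batf3, the partner factor of IRF8 in cDC1, rose from 0.755 ± 0.047 to 15.6 ± 1.7 kb, Clec9a, a receptor for dead cells, from 3.16 ± 0.39 to 28.5 ± 6.2 kb, and Xcr1, the chemokine receptor of cDC1, from 2.82 ± 0.36 to 12.6 ± 3.3 kb. Cd8a, Tlr3 and Tlr11, a surface marker and sensors of nucleic acid and of parasites, covered 8.25 ± 0.93, 5.28 ± 0.32 and 10.1 ± 0.079 kb in cDC1 and were listed at 0 in LMPP.

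Pan-DC genes were higher as well, in 13 of 18 cases, while plasmacytoid DC genes had no camera call. Zbtb46, a factor of classical dendritic cells, rose from 1.15 ± 0.6 to 26.4 ± 5.7 kb (log2 difference 3.69 ± 0.38, adjusted p = 3.07e-05), and Ciita, the transactivator of MHC class II genes, from 0.361 ± 0.51 to 20.1 ± 0.33 kb. H2-Ab1 and H2-Eb1, MHC class II chains, rose by 2.30 ± 0.20 and 1.82 ± 0.34, and Cd86 and Cd83, costimulatory molecules, by 3.37 ± 0.24 and 2.59 ± 0.22. Zfp366, a zinc finger factor of dendritic cells, rose by 4.48 ± 0.33 and Adam19, a metalloprotease, by 4.23 ± 0.57. Lgals3, which encodes galectin-3, Cd36, a scavenger receptor, P3h2, a collagen hydroxylase, and Slc9a7, an ion exchanger, covered 15.9 ± 1.6, 18.6 ± 1.1, 29.5 ± 5.2 and 17.0 ± 1.8 kb in cDC1 and were listed at 0 in LMPP.

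Genes lower in cDC1 included several of the HSC and multipotent progenitor list, the only list lower as a group. Erg, an ETS factor of stem cells, fell from 36.4 ± 3.6 to 0.796 ± 0.087 kb (log2 difference -4.38 ± 0.12, adjusted p = 3.43e-09). Meis1, a homeobox factor of stem cells, fell from 28.4 ± 4.2 to 1.62 ± 0.20 kb, and Hoxa9 from 16.9 ± 0.31 to 0.637 ± 0.17 kb. Mecom and Cd34, a regulator and a surface marker of stem cells, fell by 3.18 and 2.49 on the log2 scale. Adgrg1, an adhesion receptor, Egfl7, a secreted protein of stem cells and endothelium, Dntt, the nucleotide transferase of lymphoid progenitors, and Mpo, the granule enzyme myeloperoxidase, covered 24.3 ± 1.5, 20.7 ± 3.8, 10.9 ± 0.85 and 3.03 ± 1.8 kb in LMPP and were listed at 0 in cDC1. Gfi1, a factor of granulocytes, and Gata2, a factor of stem and mast cells, covered 5.34 ± 0.29 and 5.13 ± 1.1 kb in LMPP and were listed at 0 in cDC1.

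As groups, cDC1 genes (20 of 20 higher, 20 adjusted over the list alone, camera adjusted p = 1.14e-16) and pan-DC genes (13 of 18 higher, 13 adjusted over the list alone, 1.65e-09) were higher in cDC1. HSC and multipotent progenitor genes were lower (16 of 22 lower and 3 higher, the counts being equal when adjusted over the list alone, 2.38e-06). These 3 lists held with an estimated correlation (adjusted p = 0.00228, 0.016 and 0.016). Procr and Esam were among the higher members of the HSC list, but with WT LSK in place of WT LMPP their differences turned to -0.06 and -0.52. The other 12 lists had no camera call, with calls in both directions or few. Higher and lower calls numbered 1 and 5 of 16 lymphoid priming, 1 and 4 of 13 plasmacytoid DC, 5 and 4 of 23 monocyte and macrophage, and 2 and 5 of 12 T and NK cell genes. They numbered 3 and 5 of 13 erythroid and megakaryocyte, 1 and 1 of 16 interferon response, 2 and 1 of 13 MHC class I presentation, 6 and 8 of 26 lineage transcription factor, and 1 and 1 of 14 housekeeping genes. Of the 19 neutrophil and granule, 12 B cell and 9 mast cell and basophil genes, 3, 2 and 1 were lower. Adjusted over the list alone, lower calls became 5 for monocyte, 6 for erythroid and 9 for lineage transcription factor genes, the higher calls of interferon and housekeeping genes were lost, and the other counts were equal.

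**Figure D3:**
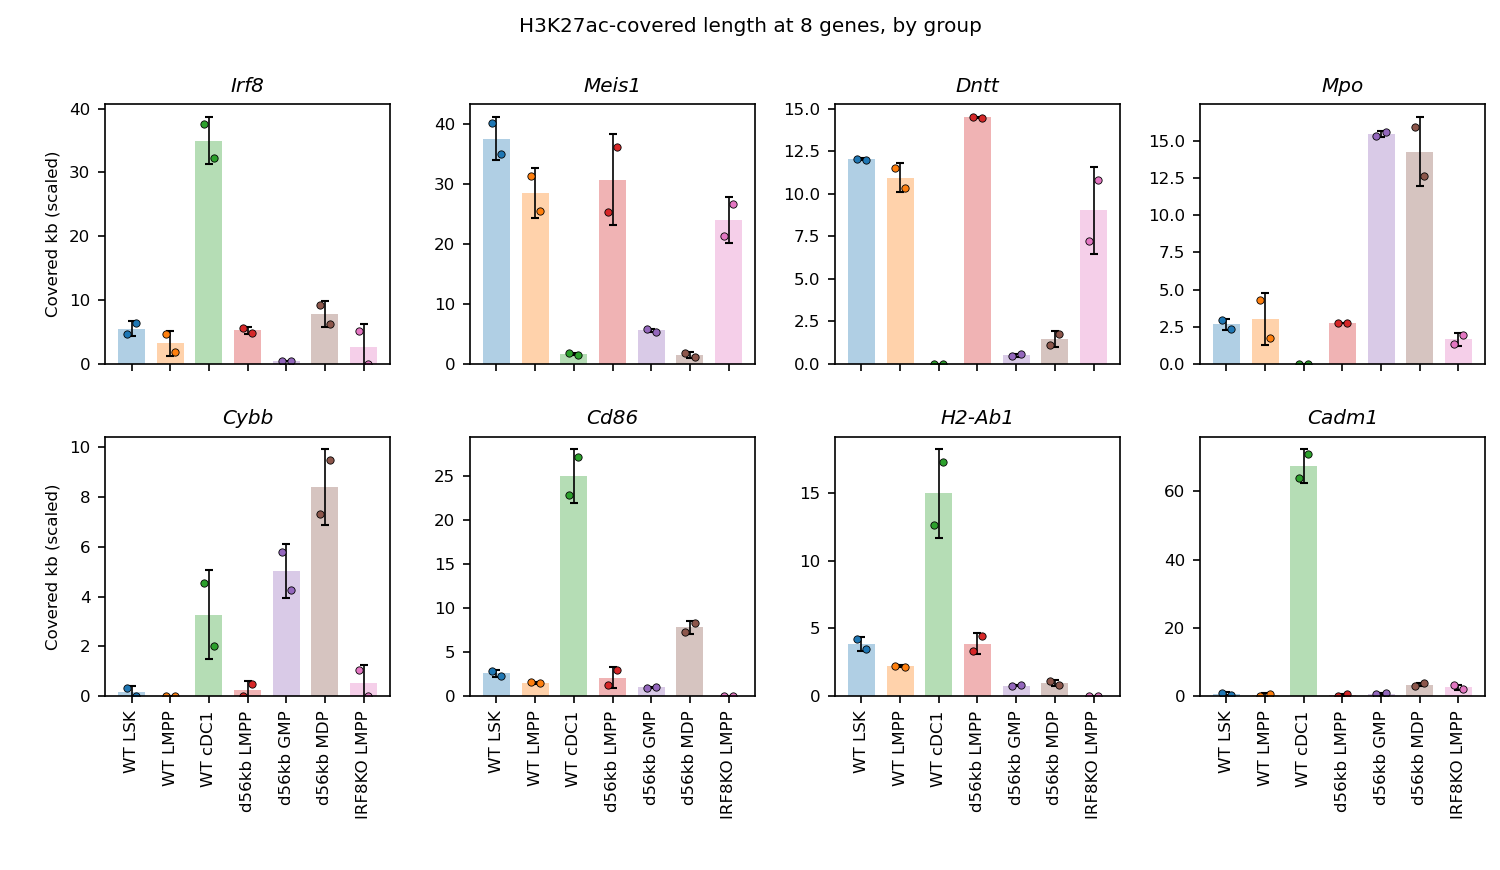
Scaled kb covered by called H3K27ac regions (y axis) at 8 genes in the 7 groups (x axis); bars are means, error bars the SD and points the libraries (n = 2 per group). Cadm1 reached 67.5 kb in WT cDC1 against 0.361 kb in WT LMPP, and Cybb 8.40 kb in d56kb MDP against 0.247 kb in d56kb LMPP.

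By limma 1834 genes were higher and 2197 lower in cDC1, and 5484 had an unadjusted p under 0.05; the median of all genes was -0.11, and 0.16 without scaling, which gave 3371 higher and 1097 lower. The count was 2665 without the first cDC1 library, 2484 in a fit of the 4 libraries and 368 with tags in called regions as a covariate. Of the 33 genes named here, 2 lost their call without each of the 4 libraries in turn. Irf8 missed the threshold only with tags in called regions as a covariate, where its difference was larger (4.39, adjusted p = 0.218).

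Within the d56kb genotype, GMP were compared with LMPP to follow the granulocyte and monocyte branch without the enhancer. Neutrophil and granule genes were higher in GMP as a group, and HSC and multipotent progenitor and pan-DC genes were lower, by both camera settings. Mpo rose from 2.74 ± 0.0084 to 15.5 ± 0.21 kb (SD, n = 2; log2 difference 2.14 ± 0.26, adjusted p = 0.000434), and Ctsg and Prtn3, neutrophil serine proteases, rose by 1.75 ± 0.28 and 1.08 ± 0.23. Ms4a3, a membrane protein of GMP, Cd14, a co-receptor for endotoxin, and Ly6c2, a surface marker of monocytes, covered 5.21 ± 0.98, 3.16 ± 0.19 and 3.3 ± 0.85 kb in GMP and were listed at 0 in LMPP. F13a1, a coagulation factor of monocytes, rose from 1.48 ± 0.0036 to 9.44 ± 0.81 kb and Cybb, a subunit of the phagocyte oxidase, from 0.247 ± 0.35 to 5.03 ± 1.1 kb. Among the highest genes, Mtus1, a microtubule-associated protein, Sgms2, a sphingomyelin synthase, and Gda, a guanine deaminase, rose by 3.57 ± 0.46, 3.46 ± 0.19 and 3.29 ± 0.40. Dstn, an actin-severing protein, App, the amyloid precursor, and Cldn15, a claudin, covered 11.2 ± 0.52, 8.88 ± 0.025 and 6.84 ± 1.4 kb in GMP and were listed at 0 in LMPP.

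The loci lower in d56kb GMP were led by Dntt, which fell from 14.5 ± 0.034 to 0.51 ± 0.094 kb (log2 difference -3.36 ± 0.20, adjusted p = 1.09e-05). Meis1 fell from 30.7 ± 7.6 to 5.58 ± 0.28 kb and Flt3, the cytokine receptor of lymphoid and dendritic progenitors, from 28.9 ± 3.5 to 9.93 ± 2.7 kb. H2-Eb1 fell from 9.87 ± 0.36 to 0.579 ± 0.82 kb, and Cd74, the invariant chain of MHC class II, from 4.86 ± 0.44 to 0.439 ± 0.0066 kb. Mn1, a transcriptional coregulator, fell by 3.24 on the log2 scale. Prdm16, a stem-cell regulator, Nkx2-3, a homeobox factor, Trpc6, a calcium channel, Lef1 and Gata3, factors of lymphoid cells, covered 7.04 ± 0.038, 8.2 ± 0.69, 8.48 ± 1.7, 3.98 ± 0.1 and 3.36 ± 0.44 kb in LMPP and were listed at 0 in GMP. Called regions near -50 and -40 kb, present in both GMP libraries, are nearer to another gene and not counted for Irf8. With them, unscaled calls from 60 kb before to 65 kb after its start covered 3.6 and 2.585 kb in GMP. In d56kb LMPP the same interval held 8.784 and 8.987 kb. Counted without these regions, Irf8 fell from 5.26 ± 0.59 to 0.439 ± 0.0066 kb (log2 difference -2.12 ± 0.62, adjusted p = 0.0443). This call ended when any 1 of the 4 libraries was left out: the differences were -2.02 and -2.21 without the first and the second LMPP library and -2.12 and -2.10 without those of GMP, with an adjusted p of at least 0.168. It also ended with a pseudocount of 200 bases, assignment within 20000 bases and tags in called regions as a covariate, and held in the other settings.

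In GMP the HSC and multipotent progenitor genes were lower (11 of 22, 15 adjusted over the list alone, camera adjusted p = 1.85e-10), as were pan-DC genes (8 of 18, 9 adjusted over the list alone, 1.93e-05). Neutrophil and granule genes were higher (8 of 19, 12 adjusted over the list alone, 4.31e-04); these 3 held with an estimated correlation (adjusted p = 0.005, 0.0412 and 0.0412). Monocyte and macrophage genes (7 of 23 higher, 12 adjusted over the list alone, 4.42e-04) had an adjusted p = 0.0769 with an estimated correlation. Erythroid and megakaryocyte genes (6 of 13 lower, 7 adjusted over the list alone, 6.19e-04) and plasmacytoid DC genes (4 of 13 lower, 5 adjusted over the list alone, 0.00261) both had an adjusted p = 0.0547 with an estimated correlation. Lymphoid priming genes (5 of 16 lower, 7 adjusted over the list alone, 0.0150) and T and NK cell genes (4 of 12 lower, 4 adjusted over the list alone, 0.0208) had an adjusted p = 0.388 and an adjusted p = 0.111 with an estimated correlation. By limma 1019 genes were higher and 928 lower, and 3531 had an unadjusted p under 0.05. Leaving out a library gave 1032 and 938 calls without the first and second d56kb LMPP library and 913 and 915 without those of GMP, and of the 26 genes named here at most 2 lost their call; with the WT and IRF8KO LMPP libraries left out of the fit the count was 3402.

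In d56kb MDP, against d56kb LMPP, monocyte genes were higher and the stem-cell program was lower. Ccl2, a chemokine that attracts monocytes, Cd14 and Ly6c2 covered 8.4 ± 0.3, 5.36 ± 0.61 and 4.55 ± 1.1 kb in MDP and were listed at 0 in LMPP. Mitf, a factor of macrophages and mast cells, rose from 0.474 ± 0.027 to 13.3 ± 2.1 kb (SD, n = 2; log2 difference 3.27 ± 0.31, adjusted p = 9.3e-05). F13a1 rose from 1.48 ± 0.0036 to 14.4 ± 0.72 kb, Cybb from 0.247 ± 0.35 to 8.4 ± 1.5 kb, and Zeb2, a zinc finger factor of myeloid cells, from 5.37 ± 0.24 to 18.9 ± 2.5 kb. Cx3cr1, a chemokine receptor of monocytes, Ccr2, the receptor of Ccl2, and Cd86 rose by 1.56 ± 0.35, 1.06 ± 0.23 and 1.57 ± 0.24. Of the cDC1 list, Cadm1, Xcr1 and Cxcl9 were called higher; Cadm1 rose from 0.247 ± 0.35 to 3.36 ± 0.55 kb and Xcr1 from 2.28 ± 0.099 to 6.2 ± 1.0 kb, while Cxcl9 covered 1.24 ± 0.53 kb and was listed at 0 in LMPP. Cpvl, a carboxypeptidase, Gda, Mtus1 and Sgms2 rose by 3.13 ± 0.49, 3.25 ± 0.40, 3.42 ± 0.46 and 3.12 ± 0.19.

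Meis1 fell from 30.7 ± 7.6 in d56kb LMPP to 1.44 ± 0.51 kb in d56kb MDP (log2 difference -3.69 ± 0.20, adjusted p = 4.95e-06), Hlf from 10.3 ± 0.32 to 1.11 ± 0.78 kb and Hoxa9 from 17.6 ± 1.3 to 2.8 ± 0.97 kb. Stxbp4, a syntaxin-binding protein, fell by 3.95 on the log2 scale, and Dntt by 2.67. Myct1, a target of MYC, Tcf7, a factor of T cells, Lax1, an adaptor of lymphocytes, Prdm16 and Nkx2-3 covered 13.2 ± 0.88, 3.05 ± 0.11, 7.48 ± 0.66, 7.04 ± 0.038 and 8.2 ± 0.69 kb in LMPP and were listed at 0 in MDP. H2-Eb1 and H2-Ab1 fell by 2.14 and 1.32. Irf8 covered 7.75 ± 2.0 kb in MDP and 5.26 ± 0.59 kb in LMPP, and did not pass (log2 difference 0.47 ± 0.62, adjusted p = 0.797). From 60 kb before to 65 kb after its start, unscaled calls covered 16.9 and 17.9 kb in MDP. In d56kb LMPP they covered 8.78 and 8.99 kb, a difference not tested.

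In MDP the HSC and multipotent progenitor genes were lower (14 of 22, 17 adjusted over the list alone, camera adjusted p = 5.28e-15) and the monocyte and macrophage genes higher (14 of 23, 16 adjusted over the list alone, 4.25e-09), and both held with an estimated correlation (adjusted p = 0.00228 and 0.0225). Erythroid and megakaryocyte genes (6 of 13 lower, 6 adjusted over the list alone, 4.74e-04) had an adjusted p = 0.0547 with an estimated correlation. T and NK cell genes (5 of 12 lower, 5 adjusted over the list alone, 0.00801) and neutrophil and granule genes (3 of 19 higher, 6 adjusted over the list alone, 0.0105) both had an adjusted p = 0.0769 with an estimated correlation. By limma 944 genes were higher and 927 lower, and 3468 had an unadjusted p under 0.05. The count was 964 and 804 without the first and the second d56kb LMPP library, 873 and 964 without those of MDP, and 3289 with the WT and IRF8KO LMPP libraries left out of the fit. Of the 30 genes named here, 5 lost their call without either LMPP library, and 5 and 4 without the first and the second MDP library.

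Against d56kb GMP, d56kb MDP carried more acetylation at pan-DC and monocyte and macrophage genes and less at HSC and multipotent progenitor genes, by both camera settings. Cd86 rose from 0.968 ± 0.11 in GMP to 7.82 ± 0.71 kb in MDP (SD, n = 2; log2 difference 2.16 ± 0.24, adjusted p = 0.00208), Cd83 from 0.935 ± 0.06 to 6.84 ± 2.6 kb and Cd74 from 0.439 ± 0.0066 to 2.43 ± 1.3 kb. Batf3 rose from 0.274 ± 0.39 to 2.65 ± 1.3 kb and Cadm1 from 0.657 ± 0.3 to 3.36 ± 0.55 kb. Il6st, the signalling chain of the interleukin-6 receptor, Psap, the precursor of lysosomal saposins, Gpr183, a receptor that guides immune cells, and Nr4a1, a nuclear receptor of monocytes, rose by 2.26 ± 0.24, 2.21 ± 0.17, 2.15 ± 0.41 and 1.16 ± 0.17. Mmp8, a neutrophil collagenase, rose by 2.36 ± 0.29, and Plxnb2, a plexin, covered 4.16 ± 0.066 kb in MDP and was listed at 0 in GMP. Zbtb16, a zinc finger factor of progenitors and innate lymphocytes, fell from 10.5 ± 0.76 to 1.21 ± 0.92 kb. Cebpe and Gfi1, factors of granulocytes, fell by 1.87 and 0.94, Meis1 by 1.45, Hoxa9 by 1.14, and Dach1, Ikzf2 and Frmd6 by 2.37, 2.17 and 2.01. Cd63, a tetraspanin of granules, and Slc28a2, a nucleoside transporter, covered 3.07 ± 0.12 and 3.38 ± 0.061 kb in GMP and were listed at 0 in MDP. Irf8 covered 0.439 ± 0.0066 kb in GMP and 7.75 ± 2.0 kb in MDP, short of the threshold (log2 difference 2.58 ± 0.62, adjusted p = 0.061). The difference was positive in each setting and passed in 8 of them, among them no scaling, an equal number of regions and a replicate block.

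Between MDP and GMP the pan-DC genes were higher in MDP (3 of 18, 6 adjusted over the list alone, camera adjusted p = 2.99e-07), as were monocyte and macrophage genes (1 of 23, 1 adjusted over the list alone, 5.17e-06). HSC and multipotent progenitor genes were lower (2 of 22, 7 adjusted over the list alone, 0.00112), and these 3 lists held with an estimated correlation (adjusted p = 0.0244, 0.0412 and 0.0412). Lymphoid priming genes leaned higher (camera adjusted p = 0.0195; adjusted p = 0.401 with an estimated correlation), with 3 members higher adjusted over the list alone. They were among 9 lists in which limma called none of 118 members; 17 had an unadjusted p under 0.05. By limma 138 genes were higher and 122 lower, and 1702 had an unadjusted p under 0.05; without scaling 116 were higher and 183 lower. The count was 22 and 29 without the first and second GMP library and 50 and 106 without those of MDP, and 14 and 8 of the 22 genes named here lost their call without a GMP and an MDP library. It was 509 and 609 with an equal number of regions, the widest and the first in deposited order, 722 with regions of both replicates, 121 with tags in called regions as a covariate, and 785 with the WT and IRF8KO LMPP libraries left out.

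Deletion of the +56 kb enhancer in LMPP was tested by comparing d56kb with WT LMPP. Hlf rose from 3.82 ± 1.1 to 10.3 ± 0.32 kb (SD, n = 2; log2 difference 1.24 ± 0.24, adjusted p = 0.0431), and Ms4a2 covered 2.26 ± 0.52 kb in d56kb and was listed at 0 in WT LMPP. Thbs1, Slc26a9, Padi3, an enzyme that converts arginine to citrulline, and Rtn4r, a receptor of neurons, covered 4.98 ± 0.79, 4.8 ± 0.73, 2.35 ± 0.055 and 2.26 ± 0.22 kb in d56kb and were listed at 0 in WT LMPP. Aacs, an enzyme of ketone body use, Chmp6, a member of the ESCRT membrane-scission machinery, Fabp12, a fatty acid binding protein, and Col16a1, a collagen, rose by 1.94 ± 0.36, 1.94 ± 0.22, 1.83 ± 0.28 and 1.72 ± 0.33. Lower in d56kb were Cdh13 (0.334 ± 0.47 against 5.71 ± 2.0 kb), Lrp1b (0.474 ± 0.027 against 6.92 ± 3.8 kb) and Lsamp (1.92 ± 0.54 against 8.74 ± 1.8 kb), and Csmd1 and Sgcd fell by 1.91 and 1.74. Cdh4, Grik1 and Nr5a2, a nuclear receptor, covered 3.35 ± 1.4, 2.75 ± 0.19 and 2.34 ± 0.78 kb in WT and were listed at 0 in d56kb LMPP. Calls at the minimum width made up 51.0 ± 7.96% in WT and 33.2 ± 0.105% in d56kb LMPP. Whether scattered narrow calls in WT LMPP account for these losses was not tested. Irf8 covered 5.26 ± 0.59 kb in d56kb and 3.26 ± 2.0 kb in WT LMPP and did not pass (log2 difference 0.63 ± 0.62, adjusted p = 0.676). The WT value includes the +56 kb element, which the deletion removes from d56kb. Assignment within 20000 bases leaves that element out, and the limma difference was then 1.12 (adjusted p = 0.391).

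The HSC and multipotent progenitor genes leaned higher in d56kb LMPP (1 of 22 called, 1 adjusted over the list alone, camera adjusted p = 0.0139; adjusted p = 0.0782 with an estimated correlation). Plasmacytoid DC genes had a camera adjusted p of 0.0362 and lymphoid priming genes of 0.0426, upward, but an adjusted p = 0.126 and an adjusted p = 0.482 with an estimated correlation. They were among 13 lists in which limma called none of 215 members, of which 32 had an unadjusted p under 0.05. Mast cell and basophil genes had 1 of 9 called higher and 2 adjusted over the list alone. The share of tags in called regions was 37.4 ± 0.903% in d56kb and 19.4 ± 6.16% in WT LMPP. The locus of Xist, whose RNA comes from the inactive X of female cells, was called in 6 of 6 d56kb libraries (1.83 ± 0.397 kb, SD, n = 6, from 3 cell types) and in 0 of the 8 others, and chromosome Y had 0 to 1 calls in d56kb libraries and 4 to 9 in the others.

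By limma 80 genes were higher and 63 lower in d56kb LMPP, and 2072 had an unadjusted p under 0.05. Without scaling the median of all genes was 0.28 and 683 genes were higher and 70 lower; the count was 436 with regions of both replicates, 35 with a replicate block, 0 in a fit of the 4 libraries (1761 at an unadjusted p under 0.05), and 0 with tags in called regions as a covariate (752). Without the first and the second d56kb library it was 2 and 1, and without those of WT LMPP 347 and 66. Of the 19 genes named here, 17 lost their call without either d56kb library, and 4 and 11 without the first and the second WT LMPP library. With WT LSK in place of WT LMPP no gene was called (699 at an unadjusted p under 0.05). The differences of Hlf, Ms4a2, Col16a1, Cdh13, Lrp1b, Csmd1, Sgcd, Lsamp and Irf8 then changed sign.

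Loss of IRF8 in LMPP was tested by comparing IRF8KO with WT LMPP. No list passed both camera settings, and the losses in IRF8KO lay at single genes of several programs. H2-Eb1 fell from 9.03 ± 0.49 to 1.67 ± 0.96 kb (SD, n = 2; log2 difference -1.96 ± 0.34, adjusted p = 0.00782) and Cd74 from 6.6 ± 0.0067 to 2.57 ± 0.2 kb, while H2-Ab1 and Cd86 covered 2.2 ± 0.057 and 1.51 ± 0.095 kb in WT and were listed at 0 in IRF8KO. Csf1r, the receptor for the macrophage growth factor, fell from 3.12 ± 0.3 to 0.494 ± 0.7 kb. Tap2 and Tapbp, of the peptide loading of MHC class I, fell by 0.81 and 1.02, Lck, a kinase of T cells, by 0.95, and Usp18, an inhibitor of interferon signalling, by 1.23. Chd3, a chromatin remodeller, Cd52, a surface glycoprotein of leukocytes, and Pard3, a polarity protein, fell by 2.29, 2.16 and 1.90. Itgam, the integrin chain CD11b, Nr1d1, a nuclear receptor of the circadian clock, and Rab22a, a small GTPase, covered 2.94 ± 1.2, 3.26 ± 0.63 and 2.89 ± 1.2 kb in WT and were listed at 0 in IRF8KO.

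Genes called higher in IRF8KO again had a larger median span, 40.7 kb against 25.8 kb for all tested and 21.9 kb for those called lower. Myo10, a myosin of cell protrusions, rose from 0.361 ± 0.51 to 5.07 ± 1.6 kb (log2 difference 2.18 ± 0.35, adjusted p = 0.00616), Fmn2, a formin, from 0.394 ± 0.56 to 4.69 ± 1.1 kb, and Nbea, a scaffold protein of neurons, from 0.361 ± 0.51 to 6.49 ± 4.8 kb. Adamts20, a metalloprotease, Dmd, which encodes dystrophin, Pparg, a nuclear receptor of fat cells and macrophages, and Tspan9, a tetraspanin, covered 4.85 ± 2.5, 3.03 ± 0.092, 3.17 ± 1.6 and 3.54 ± 0.82 kb in IRF8KO and were listed at 0 in WT LMPP. Cadm1, with a span of 332 kb, rose from 0.361 ± 0.51 to 2.53 ± 0.79 kb. Calls at the minimum width made up 64.5 ± 1.61% in IRF8KO and 51.0 ± 7.96% in WT LMPP. Irf8 covered 2.58 ± 3.6 kb in IRF8KO and 3.26 ± 2.0 kb in WT LMPP and did not pass (log2 difference -0.70 ± 0.62, adjusted p = 0.545); its difference was 0.02 with assignment within 20000 bases, 0.62 without the second IRF8KO library and, past the threshold, -2.05 without the first.

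As a group the pan-DC genes were lower in IRF8KO LMPP (4 of 18, 4 adjusted over the list alone, camera adjusted p = 0.00873), though with an adjusted p = 0.115 with an estimated correlation; Fisher's test of the calls gave an adjusted p of 0.0555. MHC class I presentation genes (2 of 13 lower, 6 lower and 1 higher adjusted over the list alone, 0.0265) and T and NK cell genes (1 of 12 lower, 3 adjusted over the list alone, 0.0488) had an adjusted p = 0.131 and an adjusted p = 0.138 with an estimated correlation. In IRF8KO 461 genes were higher and 565 lower by limma, and 2861 had an unadjusted p under 0.05. Total tags and covered length were lower in IRF8KO (1.36 ± 0.150 against 2.82 ± 1.16 M, and 18.0 ± 0.509 against 23.6 ± 1.96 Mb). With an equal number of regions 133 of the 461 genes called higher remained so, of 309 still tested, and 250 of the 565 called lower, of 505 still tested. Without scaling the median of all genes was -0.15 and 13 genes were higher and 141 lower; none was called in a fit of the 4 libraries (1126 at an unadjusted p under 0.05) or with tags in called regions as a covariate (1774), and 2557 with WT LSK in place of WT LMPP. Without the first and the second IRF8KO library the count was 2200 and 2318. Of the 24 genes named here, 7 and 2 lost their call without the first and the second WT LMPP library, and 1 and 4 without those of IRF8KO.

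IRF8KO and d56kb LMPP were compared directly to test whether the mutants differ. No list passed both camera settings, and the losses in IRF8KO again lay at single genes. H2-Ab1 and Itgam covered 3.87 ± 0.78 and 5.26 ± 1.5 kb in d56kb and were listed at 0 in IRF8KO LMPP, as were Cd86 (2.1 ± 1.2 kb in d56kb), Cebpe (2.65 ± 1.3 kb), Ms4a2 (2.26 ± 0.52 kb), Pf4, a platelet chemokine (1.4 ± 0.68 kb), and Pou2f2, an octamer factor of B cells (4.19 ± 0.59 kb). H2-Eb1 fell from 9.87 ± 0.36 to 1.67 ± 0.96 kb (SD, n = 2; log2 difference -2.07 ± 0.34, adjusted p = 0.00403), Csf1r from 4.16 ± 0.098 to 0.494 ± 0.7 kb and Itgax, the integrin chain CD11c, from 4.46 ± 0.014 to 1.02 ± 1.4 kb. Hlf, Gata2, Angpt1, a ligand of the stem-cell receptor Tie2, and Runx3 fell by 1.08, 1.41, 1.63 and 0.76. Il18r1, a chain of the interleukin-18 receptor, Metrnl, a secreted protein, and Cds2, a lipid synthesis enzyme, fell by 2.27, 2.27 and 2.30. Higher in IRF8KO were Cdh13 (12.6 ± 4.2 against 0.334 ± 0.47 kb), Ptprd, a receptor phosphatase of neurons (10.1 ± 1.7 against 0.493 ± 0.7 kb), Cntn5, a neuronal adhesion protein (8.1 ± 1.7 against 0.247 ± 0.35 kb), Car10 (7.58 ± 0.94 against 0.247 ± 0.35 kb) and Ntrk3, a neurotrophin receptor (6.91 ± 2.8 against 0.247 ± 0.35 kb). The median span was 58.8 kb for genes called higher and 24.8 kb for those called lower. Calls at the minimum width made up 64.5 ± 1.61% in IRF8KO and 33.2 ± 0.105% in d56kb LMPP. Irf8 covered 2.58 ± 3.6 kb in IRF8KO and 5.26 ± 0.59 kb in d56kb, and did not pass (log2 difference -1.33 ± 0.62, adjusted p = 0.187), but passed without the first IRF8KO library (-2.69) and without scaling (-1.81).

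Between the mutants 6 lists were lower in IRF8KO by camera, and none held with an estimated correlation. Lymphoid priming genes (4 of 16 lower, 8 adjusted over the list alone, 0.00460) had an adjusted p = 0.317 with an estimated correlation, and pan-DC genes (5 of 18 lower and 1 higher, 8 lower and 1 higher adjusted over the list alone, 0.00873) an adjusted p = 0.115 with an estimated correlation. Erythroid and megakaryocyte genes (2 of 13 lower, 2 adjusted over the list alone, 0.0220) had an adjusted p = 0.131 with an estimated correlation, and HSC and multipotent progenitor genes (4 of 22, 7 adjusted over the list alone, 0.0265) an adjusted p = 0.111 with an estimated correlation. Plasmacytoid DC genes (2 of 13 lower and 1 higher, 4 and 1 adjusted over the list alone, 0.0265) and T and NK cell genes (2 of 12 lower, 2 adjusted over the list alone, 0.0286) had an adjusted p = 0.115 and an adjusted p = 0.116 with an estimated correlation. By limma 985 genes were higher and 937 lower in IRF8KO, and 4220 had an unadjusted p under 0.05; 1864 calls lay outside chromosomes X and Y. The libraries differed in the share of tags in called regions (18.2 ± 0.576 against 37.4 ± 0.903%) and at Xist as above. Without scaling the median of all genes was -0.40 and 423 genes were higher and 4219 lower; none was called in a fit of the 4 libraries (3060 at an unadjusted p under 0.05) or with tags in called regions as a covariate (932). The count was 535 and 532 without the first and the second d56kb library and 3194 without the second IRF8KO library. Of the 23 genes named here, 8 and 6 lost their call without the first and the second d56kb library, and 1 without the second IRF8KO library.

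The mutants shared 18 genes called higher and 33 called lower against WT LMPP. Independent lists of these sizes would share 2.44 and 2.35 genes, but both comparisons used the same WT LMPP libraries. Simulated data with no effect and shared WT libraries gave a mean of 31.2 (highest 41) and 28.3 (highest 39) shared genes, so the overlap was not larger than the shared control gives.

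Regions called in both libraries of 1 LMPP genotype and in neither of another were counted next. Against WT LMPP, d56kb LMPP gained 3121 regions and lost 142, with 11113 regions called in all 4 libraries; mixed splits of the same libraries gave 337 to 453. The widest gained regions lay in Maml3, a coactivator of Notch signalling (chromosome 3, 51726770 to 51733364), near Slc26a9 (chromosome 1, 131735815 to 131741152) and in Cux1, a homeobox factor (chromosome 5, 136392169 to 136398456). Among the widest lost regions, 1 lay in Ddx3y, an RNA helicase gene of chromosome Y (1284923 to 1287302), 1 near Ndst1 on chromosome 18 (60756501 to 60759746) and 3 had no gene within 100000 bases. These 3, on chromosomes 2 and 9, were also among the 5 widest gained in IRF8KO against d56kb LMPP, all 5 without such a gene. Calls were not filtered here for sites of unreliable mapping. IRF8KO LMPP lost 1440 regions and gained 359 against WT LMPP, with mixed splits at 434 to 518. The widest lost regions lay in Crim1 (chromosome 17, 78244554 to 78249625), near Trim25 (chromosome 11, 89022312 to 89029903), and in Plec, Map3k14 and Pip4k2a. The widest gained lay in Hmga2 (chromosome 10, 120474358 to 120478215). Against d56kb LMPP, IRF8KO LMPP lost 5047 regions, the widest in Rab37 (chromosome 11, 115153498 to 115160304), and gained 156, with mixed splits at 243 to 368. The 142 regions lost in d56kb and the 359 and 156 gained in IRF8KO were fewer than in any mixed split. These sets did not exceed the spread between replicates. The larger sets went with covered length, 36.6 ± 2.17 Mb in d56kb, 23.6 ± 1.96 Mb in WT and 18.0 ± 0.509 Mb in IRF8KO LMPP. That difference between libraries cannot be separated from the genotype.

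The 142 regions counted as lost from d56kb LMPP were less often sites of IRF8 binding in cDC1 or Mo than regions called in all libraries. Being fewer than in any mixed split, they cannot show what is lost with the enhancer. For IRF8KO LMPP a difference between lost and kept regions was absent once width was allowed for. For d56kb, 12.0% of 142 lost regions overlapped an IRF8 peak, against 25.6% of those kept (odds ratio 0.396, Fisher exact p = 9.22e-05), and the odds ratio was 0.509 (p = 0.00914) when stratified by called width. For IRF8KO it was 21.7% of 1440 against 26.7% (odds ratio 0.764, Fisher exact p = 8.08e-05), but the direction turned with stratification by width (odds ratio 1.12, p = 0.172), lost regions having a median width of 2113 bases against 3277.5 for kept ones. Against d56kb, 18.5% of regions lost in IRF8KO and 26.1% of kept regions overlapped an IRF8 peak (odds ratio 0.641, Fisher exact p = 1.38e-24), with an odds ratio of 0.976 when stratified (p = 0.673). Set against gained regions instead, regions lost in IRF8KO overlapped IRF8 peaks more often (odds ratio 1.36, Fisher exact p = 0.0497, against WT LMPP and 1.74, p = 0.0268, against d56kb LMPP; not stratified by width). For d56kb against WT LMPP this odds ratio was 0.706 (Fisher exact p = 0.199). The gained regions of IRF8KO were also fewer than in any mixed split. Without the first and the second WT LMPP library the odds ratio of lost against kept regions was 0.0588 and 0.100 for d56kb and 0.151 and 0.267 for IRF8KO, without those of d56kb it was 0.577 and 0.554, and without those of IRF8KO 0.788 and 0.843. The region counts rest on single libraries. Without the first and the second d56kb library, d56kb lost 327 and 270 regions and gained 8864 and 10620 against WT LMPP, and without the first and the second WT LMPP library it lost 12209 and 5731 and gained 5098 and 4665. IRF8KO lost 2625 and 2815 and gained 11645 and 11661 without its first and second library, and lost 14664 and 8480 and gained 687 and 612 without those of WT LMPP. Against d56kb, IRF8KO gained 10801 and 10862 without its first and second library, and lost 11050 and 12826 and gained 240 and 231 without those of d56kb. With an equal number of regions per library, d56kb lost 260 and gained 1203, IRF8KO gained 238, and IRF8KO lost 2372 against d56kb; where the call had to cover at least 50% of a region, d56kb lost 78 and IRF8KO gained 142.

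IRF8 peaks were called in larger number in cDC1 than in Mo, and CEBPA peaks in larger number in Mo. The cDC1 libraries held 25170 and 25916 IRF8 peaks, of which 19295 were reproducible, and the Mo libraries 5133 and 6321, of which 4201 were reproducible. CEBPA gave 166 and 72 peaks in cDC1, with 2 reproducible, and 19705 and 17827 in Mo, with 15178 reproducible. Of the reproducible IRF8 peaks of Mo, 82.5% (3466 of 4201; 95% interval 81.3 to 83.6%) overlapped a reproducible cDC1 peak, against a mean of 0.785% in random placements (permutation p = 0.001, the smallest they can give). This left 15829 peaks of cDC1 alone and 735 of Mo alone, of which 363 met no call of either cDC1 library. Tags in IRF8 peaks made up 5.71 ± 0.409% in cDC1 and 2.20 ± 0.0104% in Mo (SD, n = 2). Tags in CEBPA peaks made up 0.0118 ± 0.00263% in cDC1 and 4.54 ± 0.871% in Mo, so that an immunoprecipitation without enrichment in cDC1 is not excluded. The peak numbers were not tested between cell types. The first part of each list in deposited order, which is not known to rank the peaks, held 9647 and 2174 reproducible IRF8 peaks in cDC1 and Mo and 8240 CEBPA peaks in Mo.

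IRF8 sites of Mo alone were the richest in CEBPA. In Mo, 45.0% of them (331 of 735; 95% interval 41.5 to 48.6%) overlapped a reproducible CEBPA peak, against 29.7% (1029 of 3466; 28.2 to 31.2%) of the sites shared with cDC1 (odds ratio 1.94, Fisher exact p = 2.80e-15). Sites of cDC1 alone overlapped CEBPA peaks of Mo in 8.65% (1369 of 15829; 8.22 to 9.10%). In cDC1, H3K27ac covered 41.8% of the reproducible IRF8 peaks (8060 of 19295; 41.1 to 42.5%), against 4.69% in random placements (permutation p = 0.001, the smallest they can give). It covered 40.9% of the sites of cDC1 alone and 45.7% of the shared sites (odds ratio 0.821, Fisher exact p = 2.07e-07), with 0.752 and 0.757 when replicate 1 and replicate 2 were left out in turn. In the first part of each list by deposited order, which is not known to rank the peaks, the odds ratio was 1.00 (Fisher exact p = 0.978). Of the sites of Mo alone, 18.1% (133 of 735; 15.5 to 21.0%) lay in H3K27ac regions of cDC1.

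**Figure D4:**
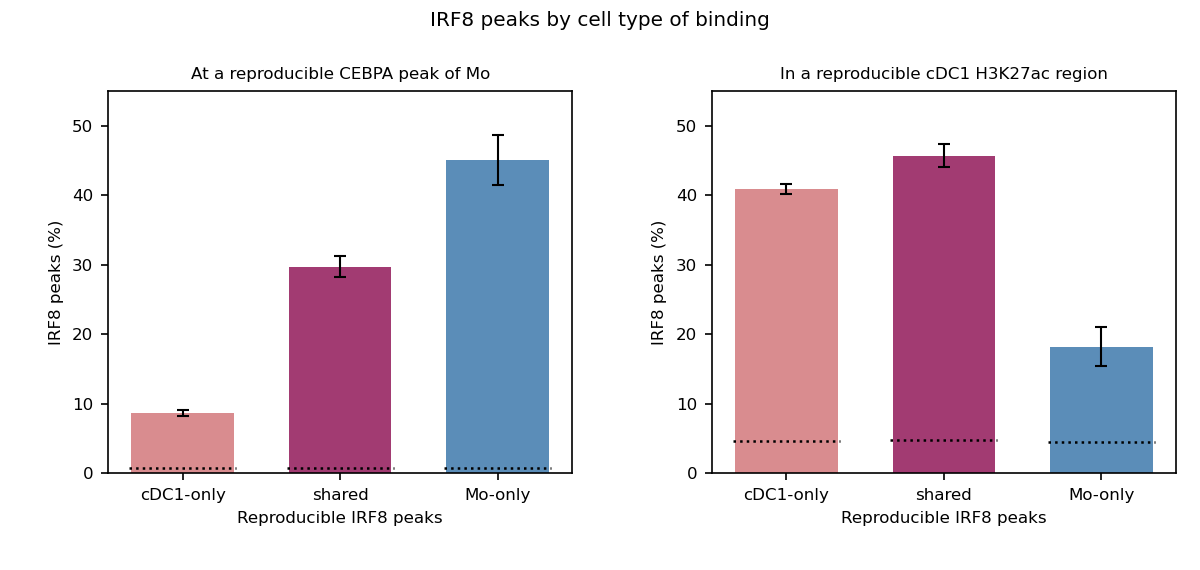
Share of IRF8 peaks (y axis, %) of the sets cDC1 alone, shared and Mo alone that overlap a reproducible CEBPA peak of Mo (left) or an H3K27ac region of both cDC1 libraries (right). Error bars are 95% Wilson intervals and dotted lines the mean of random placements; CEBPA overlap was 8.65, 29.7 and 45.0%.

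CEBPA peaks of Mo lay at nearly every monocyte gene: 23 of 24 monocyte and macrophage genes had one, against 31.4% of all genes (Fisher exact adjusted p = 2.73e-09). F13a1 had 9 CEBPA peaks, Zeb2 7, Cybb 4 and Cd14 3, and Klf4, a factor of monocytes, 3. Neutrophil and granule genes (17 of 22, adjusted p = 9.72e-05), lineage transcription factor genes (22 of 26, 4.67e-07), pan-DC and cDC1 genes (13 of 20 each, 0.0119) and lymphoid priming genes (12 of 19, 0.0192) also carried CEBPA peaks more often than other genes. Cd86 had 9 and Cebpa itself 4. The genes with the most CEBPA peaks were Lpp (23), Foxp1 (22), Trps1 (17) and Akap13 (16), with spans of 236 to 599 kb.

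IRF8 sites of cDC1 alone lay at 17 of 20 cDC1 genes and 17 of 20 pan-DC genes, against 31.1% of all genes (adjusted p = 8.30e-06 each), and at 22 of 26 lineage transcription factor genes (4.67e-07). Monocyte and macrophage genes also held such sites, in 14 of 24 cases (Fisher exact adjusted p = 0.0227). Cadm1 had 13 such sites, Flt3 and Cd86 had 6 each, Batf3, Zbtb46, Cybb and Irf8 4 each, and Ciita 3. Sites shared with Mo lay at 15 of 26 lineage transcription factor genes (4.29e-07), 13 of 24 monocyte and macrophage genes (4.41e-06) and 8 of 14 MHC class I presentation genes (2.87e-04), against 11.3% of all genes. They also lay at 8 of 20 cDC1 and 8 of 20 pan-DC genes (0.00526) and 8 of 24 HSC and multipotent progenitor genes (0.0149), with 2 at Cd74 and 2 at Ly6c2. Sites of Mo alone were more frequent at neutrophil and granule genes (4 of 22, 0.0130), lineage transcription factor genes (4 of 26, 0.0200) and lymphoid priming genes (3 of 19, 0.0485) than at all genes (2.81%). The most shared sites lay at Elmo1 (8), an engulfment protein, and Kctd12 (7). Irf2, a repressor of interferon genes, Dock10 and Lpp followed with 6 each. Sites of cDC1 alone were most numerous at Etv6 (22), an ETS repressor, and Foxp1 (20). Those of Mo alone were most numerous at Bach2, a lymphoid repressor, Rnf220 and Sgms2 (3 each). Some of these genes were long (Etv6 234 kb, Foxp1 597 kb) and others short (Kctd12 6.06 kb), and the list tests did not account for span.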

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

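The tests of gene span, of an equal number of regions and of sequencing depth in the IRF8 libraries were chosen only after the result was seen.

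IRF8 had 19816 more peaks in cDC1 than in Mo as a mean of 2 libraries, and CEBPA had -18647, so the 2 factors moved in opposite directions between the same cell types in every library. The difference between the factors was not tested. Peaks of CEBPA in cDC1 held 0.0118 ± 0.00263% of tags (SD, n = 2), so that libraries without enrichment are not excluded there. The smaller number of IRF8 peaks in Mo does not follow from sequencing depth, since the Mo libraries held 1.54 M more tags on average. The second Mo library, the deepest at 16.1 M tags, gave 6321 peaks and the second cDC1 library, the shallowest at 12.3 M, gave 25916. A weaker enrichment at the same sites stays open: 91.4% of the reproducible Mo peaks met a call of a cDC1 library, between the 95% expected of that explanation and the 80% that would exclude it, and tags in peaks were 2.20% in Mo against 5.71% in cDC1. Sites bound in Mo and not in cDC1 may exist as well, as 363 peaks of Mo met no cDC1 call. These cannot be told apart with 2 libraries per cell type, from different organs and without input for the IRF8 calls.

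The +56 kb element of Irf8 had a call in both WT LMPP libraries and in neither IRF8KO LMPP library. Lower depth of the IRF8KO libraries could account for it. Total tags were 1.36 ± 0.150 M, against 2.82 ± 1.16 M in WT LMPP (SD, n = 2). The share of tags in called regions lay within the spread of WT LMPP (18.2 ± 0.576 against 19.4 ± 6.16%). There were 2398 regions called in both WT LMPP libraries and no wider there than 809 bases. Of these, 34.5% (95% interval 32.7 to 36.5%) were missing from both IRF8KO libraries. This was short of the 50% set for lower depth and enrichment as a cause, and above the 5% that would exclude them. A loss of IRF8 at regions it binds could account for the missing call as well. Regions with a reproducible IRF8 peak were missing in 36.5% (158 of 433) and those without in 34.1% (670 of 1965), which did not separate them (Fisher exact p = 0.343). The +56 kb element itself had an IRF8 call only in the second cDC1 and the first Mo library. It thus counts among the regions without a reproducible peak, so this test does not bear on it directly. The explanations cannot be told apart from a single window in 2 libraries.

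Genes called higher in IRF8KO than in WT LMPP had a larger median span than all tested genes, as did called genes in other comparisons. With an equal number of regions 28.9% of the 461 genes kept their call, and 309 of them were still tested. This does not single out the number of regions as a cause, since the IRF8KO libraries had no more regions than WT LMPP on average (23676.5 ± 197 against 24957.5 ± 4241). Keeping the 16469 widest also removes the narrowest calls first. Calls at the minimum width made up 64.5 ± 1.61% in IRF8KO, and only a part of them was removed. Narrow calls scattered over long genes in libraries of low enrichment cannot be told apart from it: the median span was 1.58 times that of all tested genes, below the 2 times set for that cause and above the 1.2 times that would exclude it. The genotype stays among the open explanations, untested on its own, because depth and covered length differed with it.

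Signal outside the gene comparisons lay at Xist, a non-coding gene, and in calls on chromosome Y. The Xist locus was covered by 1.66 and 1.38 kb in the d56kb LMPP libraries, 1.81 and 1.52 kb in d56kb GMP and 2.21 and 2.39 kb in d56kb MDP, and by none in the other 8. Chromosome Y had 4 and 5 calls in WT LSK, 5 and 6 in WT LMPP, 6 and 5 in WT cDC1, and 9 and 6 in IRF8KO LMPP. By these marks the d56kb cells looked female and the others male, which comparisons of d56kb with other genotypes cannot separate from the deletion.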

How the results depend on the processing

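The settings regions of both replicates, deposited order, tags in called regions as covariate, WT and IRF8KO LMPP left out, WT LSK in place of WT LMPP, genes on X and Y left out and stratification by width were chosen only after the results were seen. A pseudocount of 200 bases, no filter, quantile normalization, assignment within 20000 bases and genes on X and Y left out kept each limma count within 1.5 times. The cause of the changes below was not tested. Simulated data gave 45 to 47% recovery of differences of 1 on the log2 scale at well covered genes, so low counts do not show that loci were alike.

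Without scaling the limma count was 4743 for WT LMPP against WT LSK, 753 for d56kb LMPP against WT LMPP, 154 for IRF8KO against WT LMPP and 4642 for IRF8KO against d56kb LMPP. A replicate block gave 109 for WT LMPP against WT LSK and 35 for d56kb against WT LMPP. Fits of the 4 libraries compared gave 0 for WT LMPP against WT LSK, d56kb against WT LMPP, IRF8KO against WT LMPP and IRF8KO against d56kb LMPP (3204, 1761, 1126 and 3060 at an unadjusted p under 0.05), and 2484 for cDC1 against WT LMPP. Regions of both replicates gave 1541, 436 and 722 for WT LMPP against WT LSK, d56kb against WT LMPP and d56kb MDP against GMP. Tags in called regions as covariate gave 0 by limma for WT LMPP against WT LSK and for the 3 comparisons of LMPP genotypes (466, 752, 1774 and 932 at an unadjusted p under 0.05), 368 for cDC1 against WT LMPP and 121 for d56kb MDP against GMP.

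With WT LSK in place of WT LMPP limma gave 0 for d56kb LMPP (699 at an unadjusted p under 0.05) and 2557 for IRF8KO LMPP. With WT and IRF8KO LMPP left out it gave 3402, 3289 and 785 for d56kb GMP against LMPP, MDP against LMPP and MDP against GMP. An equal number of regions gave 509 (widest) and 609 (deposited order) for d56kb MDP against GMP. For d56kb against WT LMPP the equal number gave 260 lost and 1203 gained regions; for IRF8KO it gave 238 gained against WT LMPP and 2372 lost against d56kb LMPP. Calls covering at least 50% of a region gave 78 lost in d56kb and 142 gained in IRF8KO against WT LMPP. The odds ratio of IRF8 binding at regions lost in IRF8KO was 1.12 when stratified by width.

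Stricter peak lists, taken by deposited order, which is not known to rank the peaks, gave 9647 and 2174 reproducible IRF8 peaks in cDC1 and Mo and 8240 CEBPA peaks in Mo, and an odds ratio of 1.00 for H3K27ac at IRF8 sites of cDC1 alone against shared ones. Camera with an estimated correlation called 12 list tests, all of them among the 36 with the preset correlation. The replicate similarity of 0.504 held with a replicate block (exact permutation p = 0.000198) and was 0.568 with an equal number of regions, and with windows of 2 kb at Irf8 1 of 110 calls changed, that of CEBPA at +32 kb in the first Mo library. The 2 other settings of the motif search were not run, like the search itself.

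Leaving out a library gave limma counts of 0 to 394 for WT LMPP against WT LSK, 2665 to 3680 for cDC1 against WT LMPP, 1 to 347 for d56kb against WT LMPP, 799 to 2318 for IRF8KO against WT LMPP and 532 to 3194 for IRF8KO against d56kb LMPP. It gave 913 to 1032 for d56kb GMP against LMPP, 804 to 964 for MDP against LMPP and 22 to 106 for MDP against GMP. Lost and gained regions ranged from 270 to 12209 and 4665 to 10620 in d56kb, from 2625 to 14664 and 612 to 11661 in IRF8KO, and from 7155 to 12826 and 231 to 10862 in IRF8KO against d56kb. The odds ratio of IRF8 binding at lost regions ranged from 0.0588 to 0.577 in d56kb and from 0.151 to 0.843 in IRF8KO. Single libraries held 25170 to 25916 IRF8 peaks in cDC1 and 5133 to 6321 in Mo, and 72 to 166 and 17827 to 19705 CEBPA peaks. The share of IRF8 peaks of Mo shared with cDC1 was 78.1 to 82.1%, the odds ratio for CEBPA at sites of Mo alone 1.31 to 1.56 and that for H3K27ac at sites of cDC1 alone 0.752 to 0.757.

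Over the 198 differences of named genes and 3105 alternatives to them, 2503 were unchanged in direction and call, 577 lost the call, 12 gained one and 13 changed sign. With WT LSK in place of WT LMPP, Esam and Procr were at -0.524 and -0.0566 in cDC1. In d56kb LMPP against WT LSK, Col16a1 was at -0.238, Cdh13 0.133, Lrp1b 0.353, Csmd1 0.351, Sgcd 0.519, Lsamp 0.427, Hlf -0.550, Ms4a2 -0.0258 and Irf8 -0.0534. Irf8 in IRF8KO against WT LMPP was at 0.0240 with assignment within 20000 bases and at 0.618 and -2.05 without IRF8KO replicates 2 and 1.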

Other observations

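The shares of factor sites acetylated over the progenitor groups, and the setting with WT LSK in place of WT LMPP, were chosen only after the results were seen. Sites bound by CEBPA in Mo were in part acetylated in d56kb progenitors: called H3K27ac regions covered 50.8 ± 0.0839% of them in d56kb GMP and 52.2 ± 6.63% in d56kb MDP, against 29.1 ± 1.39% in d56kb LMPP (SD, n = 2). The share was 35.0 ± 2.35% in WT LSK, 20.3 ± 0.186% in WT LMPP, 31.1 ± 5.89% in WT cDC1 and 14.9 ± 0.303% in IRF8KO LMPP. IRF8 sites shared by cDC1 and Mo were covered in 44.0 ± 6.77% in d56kb MDP, 32.0 ± 0.510% in d56kb GMP, 26.7 ± 1.26% in d56kb LMPP and 49.2 ± 10.0% in WT cDC1.

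The ratio of IRF8 sites of cDC1 alone to those of Mo alone, by the share acetylated, compares site sets within a library. Whether it depends on depth or enrichment was not tested. The ratio was 2.34 ± 0.135 in WT cDC1, 1.01 ± 0.00751 in d56kb LMPP, 0.976 ± 0.0378 in WT LMPP, 0.927 ± 0.0197 in WT LSK, 0.888 ± 0.0305 in IRF8KO LMPP, 0.646 ± 0.00363 in d56kb GMP and 0.530 ± 0.00557 in d56kb MDP (SD, n = 2). The groups of GMP and MDP thus carried more of the mark at sites of Mo alone, in both libraries of each. No test was run on these ratios, and WT GMP and MDP were not analysed here.

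Thbs1, Slc26a9, Hlf and Ms4a2 were called higher in WT LSK and in d56kb LMPP than in WT LMPP, and Cdh13, Lrp1b, Csmd1 and Lsamp lower. Both comparisons used the same WT LMPP libraries with opposite sign, which by itself brings such genes about, so that no cause follows from them. With WT LSK in place of WT LMPP, 0 genes were called between d56kb LMPP and the reference by limma (699 at an unadjusted p under 0.05).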
